A study of Ovis aries with 118 samples.

How the data were processed

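RNA of mammary epithelial cells of sheep (Ovis aries) was compared on Agilent 2-colour arrays of 15008 probes, 50 of which were spotted 5 times. The 60 RNAs came from 12 numbers, 6 of each line, in 5 conditions, and 56 of them were labelled with both dyes on a pair of dye-swapped arrays. The other 4 RNAs have 1 dye each, since 116 of the 118 listed samples have a scanner file. The same 6 pairs of numbers, a High-SCS and a Low-SCS number each, shared arrays in every condition. The 58 arrays lay on 8 slides, 4 to 8 arrays per slide, and were scanned on 2 days, 30 on the first and 28 on the second. Per the file headers, the scanner files give the signal and background intensity of each spot in each channel, from Agilent Feature Extraction 9.5.3.1. The authors' value table holds normalised intensity on a linear scale, made with Feature Extraction and limma according to the labels. It fills 4245 of 15744 rows. The medians of its columns differ between conditions (Tref 274.7 to 279, T1Sa 267.3 to 275, T1Sp 228.2 to 228.8, T5Sa 227.6 to 267.6, T5Sp 228.5 to 279), and some columns lie at the level of another condition, so how the columns were grouped for its normalisation is not known. It was used as an alternative only; one array was left out of it because its columns matched neither channel of the scanner file.

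Intensities were processed in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8). The background was corrected by normexp with an offset of 50, followed by loess within arrays and Aquantile normalisation between arrays. Repeat spots were averaged, 536 control spots were removed, and each RNA was given the mean of its channels after a dye effect had been taken out for each probe. A probe was tested when it was well above background in at least 50% of the RNAs of at least 1 group of line and condition, which left 8947; 5224 were so in every RNA, and 103 lacked a value in some RNA. The number of arrays limits the precision, and the signal over background limits what a dim probe can show. A linear model with a mean for each line and condition was fitted, with the RNAs that shared arrays as a random block (correlation 0.237), and tested with limma's moderated statistic, 2-sided, with Benjamini-Hochberg adjustment in each comparison and a threshold of 0.05. Each stimulation was compared with Tref, the arms with each other at each time, the lines in each condition and over all, and the response to each stimulation between the lines. The time at which Tref was taken is not given in the labels, so a change against it includes any change with time in culture.

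The 12 numbers recur in every condition, and the normalised profiles of a number resembled each other across conditions in 12 of 12 numbers for each of the 6 pairs of conditions compared here (correlation over 0.1), and in 10 of 12 for T1Sp with T5Sa, which were not compared. A fit with the number as a fixed block (correlation of the shared arrays 0.384) is therefore given beside each count. The main values are without it because that model was fixed before the data were examined, as were the comparisons, the gene lists, the rule for naming genes and the alternatives, except for those listed at the end of this section as added. A probe not well above background in any RNA of Tref has no measured starting level, so its fold is given as a lower bound, the treated mean over a Tref mean in which each channel was raised to at least the lowest value of any spot well above background in that channel.

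Gene symbols came from the names in the scanner files, updated with a current table of sheep genes, which gave names to 1409 probes. Where a gene had several probes (221 of the 398 genes tested), the brightest stood for it. For each stimulation the genes named are the 8 highest and 8 lowest among those that passed, and up to 4 measured members of each list, those with the smallest p. For the other comparisons they are the 8 highest and 8 lowest, and for interactions 5 of each. Some genes that meet this rule are not described here. Of 28 gene lists written from general knowledge, 26 had a measured member and the 9 with at least 5 were tested with cameraPR against the 398 genes at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation.

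The pipeline was tested on simulated data built on these arrays' layout, with 6615 tested probes and 50 probes changed at each size. The simulation gave RNAs that shared arrays a correlation of 0.2, but it had no effect of the number and the same spread in every condition. The real numbers resembled themselves across conditions. The rates below may therefore not carry over, and they cannot compare the fits with and without the number as a block. For T5Sa against Tref, 15 of 50 changes of 0.25 on the log2 scale were called, 40 of 50 at 0.5, 46 of 50 at 1 and 50 of 50 at 2, and 12 of 163 calls (7.36%) were false. With the block, 14 of 166 calls (8.43%) were false. For a line difference within T5Sa, 6, 29, 48 and 50 of 50 were called, with 5 of 138 calls (3.62%) false. A comparison without planted changes gave 0 calls, an interaction without planted changes 1, and 0 of 20 lists without a planted shift were called. In the real data 3 lists were called in 54 tests over 6 comparisons. For other splits of the samples, 1 split of each comparison was drawn and the list calls were summed over the 6. Of 99 such sums, 70 held at least 1 call.

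The alternatives were Feature Extraction's processed signals, median scaling, quantile normalisation, no filter on dim probes, probes well above background in every RNA, the value table, each dye alone, no block for shared arrays, the array pair as a fixed term, the slide as a random block, the number as a block, and leaving out each number. Added after the data had been seen were the arrays of each scan day alone, and leaving out the 6 arrays whose channels resembled each other (correlation over 0.6), with and without the number as a block. Single slides were fitted too, 6 per stimulation, with 2 or 4 channels of the stimulation against 2 or 4 of Tref. These slide fits are not among the alternatives, and they rest on few RNAs.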

Results

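Gene expression was measured in cultured mammary epithelial cells of sheep, in a study of how these cells bear on predisposition to udder infection by Staphylococcus aureus. The cells came from 2 lines, High-SCS, labelled as highly susceptible, and Low-SCS, labelled as less so. Each line was represented by 6 numbers in the labels, named here by line and number, and each number by 5 RNAs: an untreated reference (Tref), 2 stimulations of 1 h (T1Sa and T1Sp) and 2 of 5 h (T5Sa and T5Sp). One arm received live bacteria and the other the soluble factors of their culture supernatant, but the labels contradict each other on which code is which, so the arms are named by code only. The 60 RNAs (n = 12 per condition, 6 per line) were read on 58 Agilent 2-colour arrays, each carrying a High-SCS and a Low-SCS RNA of the same condition. The labels do not say whether a number is an animal or a culture. A p-value of the main fit sets a difference against the spread between the numbers within a group, pooled over all groups. It does not measure how a change varies from number to number. The fit with the number as a block compares within numbers, with a spread that is pooled too.

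Between 36.9% and 61.3% of spots were well above background in the Cy3 channel (median 52.0%) and between 31.0% and 50.2% in Cy5 (median 42.8%). Median signals ran from 38.2 to 60.5 in Cy3 over backgrounds of 31 to 38, and from 75.4 to 98.2 in Cy5 over backgrounds of 61 to 69. Of 15008 probes, 8947 were bright enough to test. A gene symbol was known for 631 of these, covering 398 genes, so the other 8316 tested probes enter the counts without a name. Changes are log2 differences of normalised intensity, with the standard error of the fit, and levels are mean ± SD of log2 intensity.

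**Figure D1:**
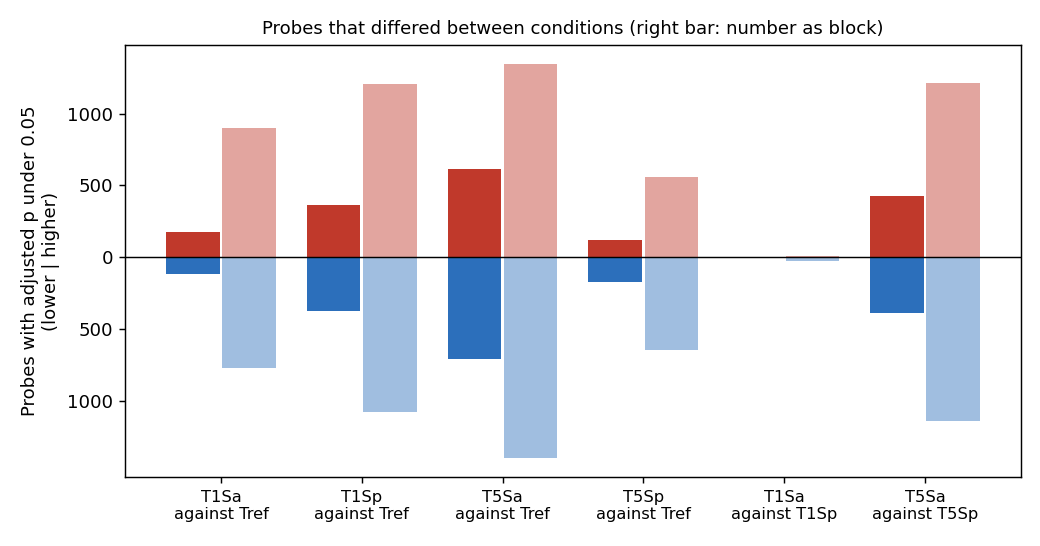
Number of probes with an adjusted p under 0.05 in each comparison of conditions, higher above the axis (red) and lower below it (blue); the left bar of each pair is the fit with only the shared arrays as a block and the right, paler bar the fit with the number as a block too. T5Sa against Tref has the tallest bars, 617 higher and 709 lower without the number as a block.

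The response to the arm coded Sa after 1 h was small. Among the named genes that passed, 4 fell. PSAP, the precursor of the lysosomal saposins, changed by -0.54 ± 0.14 (n = 12 each, adjusted p = 0.0259, lower in 11 of 12 numbers), and ITGB5, an integrin beta chain, by -0.33 ± 0.09 (adjusted p = 0.0252, lower in 12). TFAP2A, a transcription factor, changed by -0.27 ± 0.08 (adjusted p = 0.0411, lower in 10), and SLC12A4, a potassium chloride cotransporter, by -0.26 ± 0.07 (adjusted p = 0.0397, lower in 12). None of the 6 measured members of the list of cytokines and chemokines passed in limma's test, over all probes or adjusted over the list alone, and 1 did with the number as a block, interleukin 18 (IL18; 0.31, adjusted p = 0.0215, higher in 11). The neutrophil attractant CXCL8 differed by 0.43 ± 0.67 (adjusted p = 0.833, with the number as a block 0.6745, higher in 12 of 12 numbers). Its standard error was 0.67 in every stimulation, since the fit pools the spread of all groups. The test therefore does not exclude a small rise shared by the numbers. No list of the 9 tested passed, the lowest adjusted p being 0.425 for glycolysis and hypoxia, whose 8 members had a median change of -0.09. That list includes the glucose transporter SLC2A1, at -0.57 ± 0.20 (adjusted p = 0.0882, lower in 11 of 12 numbers; with the block the adjusted p was 0.00335).

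Over all probes, limma called 292 changed in T1Sa, 174 higher and 118 lower, with a median size of 0.32 and none over 1 on the log2 scale; 1618 had an unadjusted p under 0.05. With the number as a block the calls rose to 1670, 899 higher and 771 lower. With the slide as a random block there were 734. Arrays of scan day 1 alone gave 1 call and those of day 2 alone 0 in limma (448 at an unadjusted p under 0.05). Single slides gave 0 to 2. Median scaling in place of loess and Aquantile ended every call (limma, 0; 981 at an unadjusted p under 0.05). The authors' value table gave 168 higher and 305 lower. The count depended on single numbers: it was 156 without High-SCS-5012, 83 without Low-SCS-5046, 163 without Low-SCS-5051, 96 without Low-SCS-5130, 132 without High-SCS-5178, 47 without High-SCS-5182 and 146 without High-SCS-5217. Of the named genes, TFAP2A lost its call for 8 of the 12 left-out numbers (adjusted p up to 0.111). SLC12A4 lost it for 7 (up to 0.14), and PSAP and ITGB5 for 4 each (up to 0.0884 and 0.0757).

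In the arm coded Sp, 3 of the 6 measured members of the list of cytokines and chemokines rose within 1 h. CXCL8 rose by 2.08 ± 0.67, from 8.66 ± 0.84 to 10.74 ± 1.35 (adjusted p = 0.0425, higher in 12 of 12 numbers). TNF, the cytokine tumour necrosis factor, was not well above background in any untreated RNA and rose at least 2.43-fold (adjusted p = 0.0253, higher in 12). Interleukin 1 alpha (IL1A) rose by 0.82 ± 0.27 (adjusted p = 0.0451, higher in 12). AREG, which encodes the EGF receptor ligand amphiregulin, rose by 1.20 ± 0.30, from 9.43 ± 0.81 to 10.63 ± 0.33 (adjusted p = 0.00768, higher in 12). Among the genes that fell were GATA3, a transcription factor of luminal mammary cells, at -0.69 ± 0.15 (adjusted p = 0.00324, lower in 12). The pro-apoptotic BAX stood at -0.63 ± 0.18 (adjusted p = 0.0211, lower in 12) and squalene epoxidase (SQLE), an enzyme of cholesterol synthesis, at -0.89 ± 0.24 (adjusted p = 0.0165, lower in 11).

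Of 29 named genes that passed in T1Sp, 13 were higher and 16 lower. The other genes with the highest rises were the metallothionein MT3 (0.57), the translation factor EIF4A2 (0.39), the interleukin 13 receptor chain IL13RA1 (0.33) and CCL25, a chemokine outside the list (0.26). The other genes with the lowest values were the centromere protein gene CENPB (-0.66), the lysosomal protease gene CTSB (-0.51), the glycolytic enzyme gene ALDOA (-0.51), a probe named for malate dehydrogenase, MDH (-0.49), and the asparaginyl-tRNA synthetase gene NARS (-0.44). These 9 genes had adjusted p-values from 0.0106 to 0.0426 and moved their way in 10 to 12 of the 12 numbers. Over the alternatives the rises came down to 0.31 (MT3), 0.15 (EIF4A2), 0.12 (IL13RA1) and 0.035 (CCL25). The falls shrank to as little as -0.145 (CENPB), -0.25 (CTSB), -0.17 (ALDOA), -0.22 (MDH) and -0.04 (NARS). The calls were lost in from 3 of 27 alternatives (MDH) to 15 of 27 (CTSB). A second probe of SQLE (-0.29), CENPB (-0.06), BAX (-0.37), MDH (-0.06), NARS (-0.03), CCL25 (0.15) and ALDOA (0.11) did not pass, so these genes rest on 1 probe each. By list, 3 of the 6 cytokines and chemokines rose and none fell, 4 adjusted over the list alone and 4 with the number as a block, but the list as a whole did not pass (adjusted p = 0.132). Of 8 glycolysis and hypoxia genes, GAPDH rose (0.19 ± 0.05, adjusted p = 0.0076, higher in 12) and ALDOA fell, and 4 passed adjusted over the list alone. PDIA4, a protein disulfide isomerase, changed by -0.31 ± 0.09 (adjusted p = 0.0282, lower in 10), and SPRY2, an inhibitor of receptor tyrosine kinase signalling, by 0.18 ± 0.06 (adjusted p = 0.0408, higher in 10). None of the 8 immediate early genes passed, and 3 did with the number as a block, MCL1 (0.35, adjusted p = 0.00624, higher in 11), FOS (0.18, adjusted p = 0.0317, higher in 9) and ZFP36 (0.25, adjusted p = 0.0287, higher in 9).

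limma called 740 probes changed in T1Sp, 365 higher and 375 lower, and with the number as a block 2279, 1203 higher and 1076 lower. The slide as a random block gave 1284, arrays of scan day 1 alone 2 and those of day 2 alone 24. Single slides gave 0 to 16. Without the 6 arrays whose channels resembled each other, 2 of which carried T1Sp RNAs, the count was 206, 81 higher and 125 lower. Median scaling, in which the median change of all probes was -0.06 (main fit 0.006), gave 4 higher and 401 lower. The value table, in which the median change of all probes was -0.24, gave 10 higher and 1836 lower. The count was 468 without Low-SCS-5046, 394 without Low-SCS-5051, 488 without High-SCS-5071 and 475 without High-SCS-5189. CXCL8 lost its call when any number but Low-SCS-5129 or High-SCS-5178 was left out (adjusted p 0.0504 to 0.0925) and IL1A for 8 of the 12 (up to 0.0955). TNF lost it without Low-SCS-5130, High-SCS-5189 or High-SCS-5217 (adjusted p = 0.0553, 0.0639 and 0.0554). BAX lost its call without Low-SCS-5046, Low-SCS-5051, High-SCS-5071 or High-SCS-5189 (adjusted p = 0.057, 0.0689, 0.0522 and 0.0685) and SQLE without Low-SCS-5051 (0.0623). AREG and GATA3 passed with each number left out. Each lost its call in 3 of 27 alternatives (adjusted p up to 0.315 and 0.429), and over all of these the changes came down to 0.96 and -0.31. SPRY2 lost its call for 9 of the 12, CTSB for 8, EIF4A2 and CENPB for 7, IL13RA1, NARS and PDIA4 for 4 and MT3 for 2 (highest adjusted p 0.114, 0.109, 0.0808, 0.086, 0.0706, 0.0778, 0.0861 and 0.0658).

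After 5 h in the Sa arm the response was wider. CXCL8 rose by 2.63 ± 0.67 to 11.28 ± 1.87 (adjusted p = 0.00549), IL1A by 1.04 ± 0.27 to 10.28 ± 0.20 (adjusted p = 0.00598), and TNF at least 2.64-fold (adjusted p = 0.00812), each in 12 of 12 numbers. The glucose transporter gene SLC2A3 rose by 2.19 ± 0.23 to 9.19 ± 0.64 (adjusted p = 5.66e-10, higher in 12). VEGFA, an angiogenic factor, rose by 0.65 ± 0.19 (adjusted p = 0.0135, higher in 10). MYC, a transcription factor that drives growth, changed by -0.89 ± 0.15 (adjusted p = 1.67e-05, lower in 12), the matricellular protein gene CCN1 by -0.62 ± 0.10 (adjusted p = 2.05e-05, lower in 12). ATP citrate lyase (ACLY), which supplies acetyl-CoA for lipid synthesis, changed by -0.44 ± 0.08 (adjusted p = 0.000126, lower in 12).

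The 6 cytokines and chemokines shifted upward as a list (adjusted p = 0.0109, median change 0.63), with 4 risen (CXCL8, IL1A, TNF and CSF2) and none fallen, and the same number adjusted over the list alone. The adjusted p was 0.111 with an estimated correlation, 0.0426 with the number as a block, 0.00757 with the slide as a block, and 0.037 and 0.00989 on the arrays of scan days 1 and 2. The call was thus lost with the estimated correlation. At the preset correlation it was kept in the 25 alternative fits that could test the list (adjusted p from 0.000784 to 0.0426). Of 4 NF-kB targets, NFKBIA, the NF-kB inhibitor, rose by 0.99 ± 0.30 (adjusted p = 0.0183, higher in 9) and the adhesion molecule gene ICAM1 by 0.54 ± 0.19 (adjusted p = 0.0434, higher in 10). With the number as a block all 4 passed as higher, the others being SOD2 (0.56, adjusted p = 0.0224) and IRF1. The pentraxin PTX3, not well above background in any untreated RNA, rose at least 1.67-fold (adjusted p = 0.0275, higher in 12). Of 8 immediate early genes, ZFP36, whose protein destabilises cytokine mRNA, rose by 0.47 ± 0.11 (adjusted p = 0.00127, higher in 11), while MYC, CCN1 and JUND fell, 4 in all adjusted over the list alone. The list did not pass (adjusted p = 0.122). The lipid droplet protein gene PLIN2 rose by 0.55 ± 0.17 (adjusted p = 0.0234, higher in 11).

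Of 48 named genes that passed in T5Sa, 25 were higher and 23 lower. MT3 rose by 0.58 ± 0.17 (adjusted p = 0.0131, higher in 11). The remaining genes with the lowest values fell in 12 of 12 numbers: VDUP1, an older name of the thioredoxin-interacting protein gene, at -0.86, BAX at -0.68, the spindle gene ASPM at -0.56, the heat shock gene HSP70.1 at -0.51 and the Wnt receptor gene FZD2 at -0.45, with adjusted p-values from 0.00282 to 0.0281. GATA3 changed by -0.44 ± 0.15 (adjusted p = 0.0405, lower in 12), IGF1R by -0.29 ± 0.10 (adjusted p = 0.0319, lower in 11) and PDIA4 by -0.28 ± 0.09 (adjusted p = 0.0327, lower in 10). The monocyte marker and endotoxin co-receptor CD14 rose by 0.24 ± 0.08 (adjusted p = 0.0478, higher in 10), whereas the other leukocyte markers differed by 0.04 (TYROBP) and 0.08 (FCER1G, not well above background in either condition) and did not pass.

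limma called 1326 probes changed in T5Sa, 617 higher and 709 lower, 26 of them by over 1 on the log2 scale. With the number as a block there were 2739, 1343 higher and 1396 lower, with the slide as a random block 1788, and on the arrays of scan days 1 and 2 alone 977 and 53. Single slides gave 0 to 593 calls, the 593 on a slide with 2 T5Sa channels, those of High-SCS-5071 and Low-SCS-5051. Median scaling, in which the median change of all probes was -0.08 (main fit -0.005), gave 88 higher and 1156 lower. The value table, in which it was -0.22, gave 99 higher and 1734 lower. NFKBIA lost its call without High-SCS-5217 (adjusted p = 0.0506) and PTX3 without Low-SCS-5130, High-SCS-5189 or High-SCS-5217 (0.0725, 0.0634 and 0.0742). CSF2 and CD14 lost theirs for 9 of the 12 left-out numbers, ICAM1 for 8, GATA3 for 7 and PDIA4 for 6 (highest adjusted p 0.116, 0.105, 0.103, 0.0997 and 0.0953). IGF1R lost its call without High-SCS-5012, High-SCS-5178, High-SCS-5182 or High-SCS-5217 (0.0829, 0.064, 0.0636 and 0.0588). HSP70.1 lost its call without Low-SCS-5127 or High-SCS-5217 (0.0735 and 0.0511), FZD2 without Low-SCS-5130 (0.0613) and PLIN2 without High-SCS-5012 or Low-SCS-5129 (0.0518 and 0.0674).

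**Figure D2:**
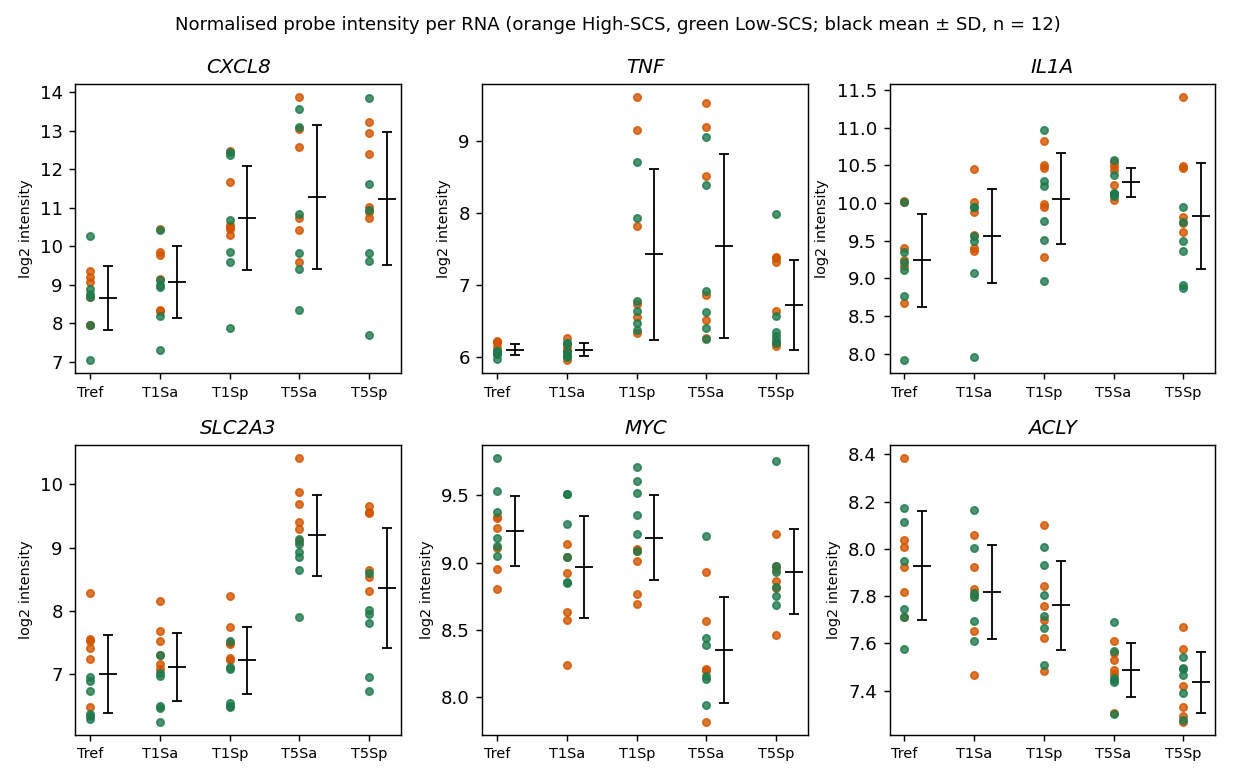
Normalised log2 intensity of 6 genes in each RNA by condition (orange High-SCS, green Low-SCS; black bar and whiskers mean ± SD, n = 12). CXCL8 lies at 8.66 ± 0.84 untreated and at 11.28 ± 1.87 in T5Sa, and SLC2A3 lies at 9.19 ± 0.64 in T5Sa.

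After 5 h in the Sp arm, CXCL8 stood at 11.24 ± 1.73, a rise of 2.58 ± 0.67 (adjusted p = 0.0173, higher in 12 of 12 numbers), and SLC2A3 rose by 1.35 ± 0.23 (adjusted p = 0.000113, higher in 12). The collagenase gene MMP1 rose by 0.87 ± 0.13, from 6.21 ± 0.18 to 7.08 ± 0.48 (adjusted p = 1.13e-05, higher in 12). Its untreated level lay near that of TNF, which was not well above background there. Over 25 alternatives the rise of MMP1 was 0.61 to 3.02, and 24 kept its call. The mitochondrial superoxide dismutase SOD2 rose by 0.77 ± 0.21 (adjusted p = 0.0265, higher in 10) and the interferon receptor chain IFNAR2 by 0.51 ± 0.11 (adjusted p = 0.00336, higher in 12). CPT1A, which admits fatty acids to mitochondrial oxidation, rose by 0.19 ± 0.05 (adjusted p = 0.00968, higher in 12). Of the fatty acid and milk fat genes, ACLY fell with a change of -0.50 ± 0.08 (adjusted p = 7.13e-05, lower in 12) and the stearoyl-CoA desaturase SCD with -0.40 ± 0.08 (adjusted p = 0.000453, lower in 12). CCN1 changed by -0.67 ± 0.10 (adjusted p = 1.44e-05, lower in 11), the hyaluronan receptor gene RHAMM by -0.67 ± 0.14 (adjusted p = 0.00109, lower in 12; a second probe, at -0.20, did not pass). ASPM changed by -0.54 ± 0.13 (adjusted p = 0.0111, lower in 12) and the Wnt receptor gene FZD3 by -0.25 ± 0.05 (adjusted p = 0.000695, lower in 12).

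These 12 were all the named genes that passed in T5Sp, 6 in each direction. Of 5 fatty acid and milk fat genes 2 fell, and the 5 had a median change of 0.03 (3 passed adjusted over the list alone), of 6 cytokines and chemokines 1 rose, and of 8 matrix proteases and inhibitors 1 rose. The block made that 2 cytokines and chemokines and 3 matrix proteases and inhibitors, IL1A among them (adjusted p from 0.287 to 0.0113, higher in 10). No list passed as a whole (lowest adjusted p = 0.0665). TNF was higher in 12 of 12 numbers, at least 1.5-fold, but did not pass (adjusted p = 0.532, with the block 0.213). Its standard error, pooled over all groups, was 0.39 in every stimulation, so the test does not exclude a rise. PTX3, higher in 12 and at least 1.74-fold, did not pass either (adjusted p = 0.0504, with the block 0.00568). limma called 292 probes, 123 higher and 169 lower, and 1207 with the number as a block, 561 higher and 646 lower. The slide as a random block gave 536 and the arrays of scan days 1 and 2 alone 199 and 13. Single slides gave 0 to 107. Median scaling gave 43 higher and 71 lower. CXCL8 lost its call without Low-SCS-5127, High-SCS-5189 or High-SCS-5217 (adjusted p = 0.0518, 0.0501 and 0.0597) and SOD2 without High-SCS-5071, Low-SCS-5127, Low-SCS-5130, High-SCS-5189 or High-SCS-5217 (0.0674, 0.0592, 0.0746, 0.0718 and 0.0803).

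**Figure D3:**
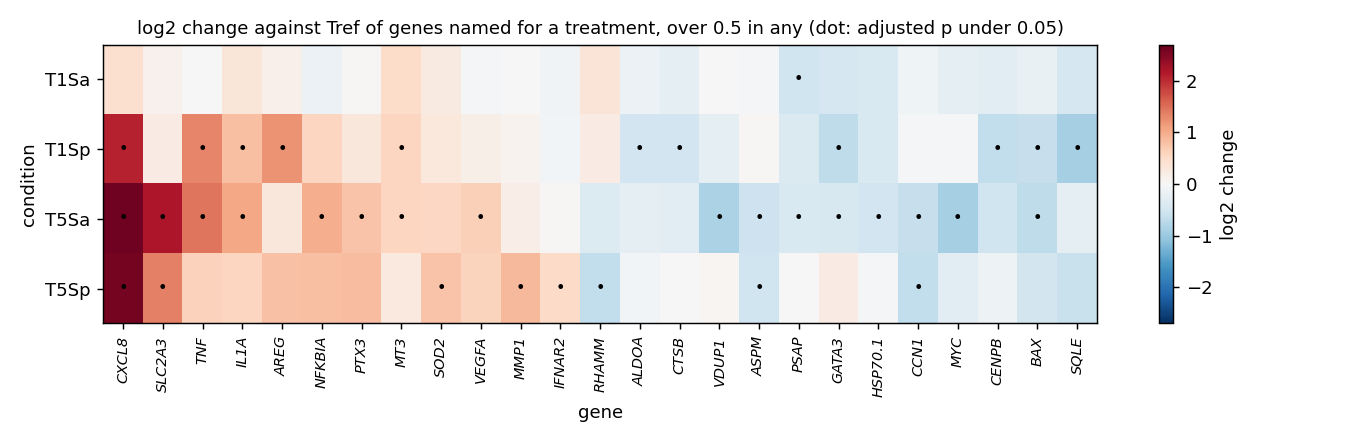
Change against Tref (log2, colour scale from blue, lower, to red, higher) of genes named for a stimulation that differed by over 0.5 in at least 1 of the 4 stimulations, in each of them; a dot marks an adjusted p under 0.05. CXCL8 carries a dot in T1Sp (2.08), T5Sa (2.63) and T5Sp (2.58), and MMP1 in T5Sp (0.87).

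The arms were compared directly at each time. At 1 h the 8 measured immediate early genes, which answer stimulation within minutes, were lower as a list in T1Sa than in T1Sp (adjusted p = 0.000295, median difference -0.17; adjusted p = 0.0019 with an estimated correlation). None of the 8 passed over all probes, and 3 did adjusted over the list alone: ZFP36 at -0.37 ± 0.11 (lower in 12 of 12 numbers), the AP-1 component gene JUNB at -0.42 ± 0.14 (lower in 12) and FOS, another AP-1 component, at -0.22 ± 0.07 (lower in 9). With the number as a block the list's adjusted p was 0.000247 and JUNB and ZFP36 passed over all probes (0.000881 and 0.0348). With the slide as a block it was 0.000236, and on the arrays of scan days 1 and 2 it was 0.000818 and 0.183. The range over 27 alternatives was 1.95e-07 to 0.183. limma called 3 probes, all lower in T1Sa and none with a gene symbol, against 704 at an unadjusted p under 0.05. Among them, chosen after their values were seen, were A_70_P048891 (-0.81 ± 0.14, adjusted p = 0.00339, lower in 12) and A_70_P026731 (-0.94 ± 0.18, adjusted p = 0.0171, lower in 12). The block raised the count to 38, 12 higher and 26 lower, and the slide as a random block to 7. limma called 0 on the arrays of each scan day (142 and 992 at an unadjusted p under 0.05) and 0 after median scaling (1132 at an unadjusted p under 0.05). The value table, with a median difference of 0.22, gave 1367 higher and 9 lower. The count was 6 without Low-SCS-5046 and 1 without Low-SCS-5129, High-SCS-5182 or High-SCS-5217, and A_70_P026731 lost its call without Low-SCS-5129, High-SCS-5182 or High-SCS-5217 (adjusted p = 0.0903, 0.0743 and 0.0775).

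At 5 h the arms differed more. SLC2A3 was higher in T5Sa than in T5Sp by 0.83 ± 0.23 (adjusted p = 0.0155, higher in 12 of 12 numbers). Also higher were the splicing factor gene SRSF3 (0.57), EIF4A2 (0.47), EEF1E1, which encodes a subunit of the aminoacyl-tRNA synthetase complex (0.45), and the lactate transporter gene SLC16A1 (0.40). So were NAMPT, an enzyme of NAD synthesis (0.24), and FZD3 (0.15). These 6 had adjusted p-values from 0.00107 to 0.0369 and were higher in 11 or 12 numbers. Lower in T5Sa were VDUP1 at -0.91 ± 0.25 (adjusted p = 0.0136, lower in 12), and MMP1 at -0.70 ± 0.13 (adjusted p = 0.000437, lower in 12), as were GATA3 at -0.66 ± 0.15 (adjusted p = 0.00325, lower in 12) and MYC at -0.58 ± 0.15 (adjusted p = 0.00655, lower in 12). They were followed by IFNAR2 (-0.49), SLC12A4 (-0.47), PSAP (-0.44) and the clock gene BMAL1 (-0.38), with adjusted p-values from 6.09e-05 to 0.0371. In all 18 named genes passed, 7 higher and 11 lower. The 8 matrix proteases and inhibitors were lower in T5Sa as a list (adjusted p = 0.0418, median difference -0.20; adjusted p = 0.383 with an estimated correlation), with MMP1 the member that passed, over all probes and adjusted over the list alone (3 passed with the number as a block). Next to it stood the protease inhibitor gene TIMP1 (-0.46) and the lysosomal protease genes CTSD (-0.33) and CTSB (-0.31), none of which passed; with the number as a block TIMP1 and CTSD did and CTSB did not (adjusted p = 0.0655). That list's adjusted p was 0.0504 with the number as a block, 0.0395 with the slide as a block, 0.15 and 0.0317 on the arrays of scan days 1 and 2 and 0.318 after median scaling. At the preset correlation, 13 of the 25 alternative fits that could test the list kept the call (0.0217 to 0.318).

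limma called 811 probes different between the arms at 5 h, 423 higher in T5Sa and 388 lower. With the number as a block there were 2347, 1210 higher and 1137 lower, with the slide as a random block 1330, and on the arrays of scan days 1 and 2 alone 638 and 20. Median scaling, with a median difference of all probes of -0.08 (main fit 0.003), gave 29 higher and 708 lower. The value table, with a median difference of -0.22, gave 47 higher and 1638 lower. SLC16A1 lost its call for 7 of the 12 left-out numbers, FZD3 for 8 and PSAP for 6 (highest adjusted p 0.095, 0.089 and 0.0964), and SRSF3 without High-SCS-5178 (0.0509).

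The line comparisons ask whether cells of the line labelled susceptible differ from the other. SLC2A3 was higher in High-SCS in T5Sp by 1.37 ± 0.26, at 9.04 ± 0.61 against 7.68 ± 0.70 (n = 6 each, adjusted p = 0.00645; a second probe, at 1.22, also passed). The sign of this and every other line difference follows the dye named in each sample's labels. In the authors' value table, 57 of 58 arrays have the values of the opposite channel under each sample, and there the difference is -1.39. SLC2A3 was also higher in High-SCS in Tref (0.82 ± 0.26, unadjusted p = 0.0025), T1Sa (0.73), T1Sp (0.70) and T5Sa (0.88), none passing after adjustment, and its response to T5Sp did not differ between the lines by limma's interaction test (0.55 ± 0.37, unadjusted p = 0.139). It lost its T5Sp call without Low-SCS-5129, Low-SCS-5130 or High-SCS-5217 (adjusted p = 0.0596, 0.109 and 0.0885). Over 26 alternatives, these among them, the call was lost in 8 and the sign changed in 1, the value table (adjusted p up to 0.481). In T5Sa an unnamed probe, A_70_P041641, chosen after its value was seen, was higher in High-SCS by 0.71 ± 0.13 (14.52 ± 0.39 against 13.81 ± 0.38, n = 6 each, adjusted p = 0.0226). It lost its call without High-SCS-5012, Low-SCS-5046, Low-SCS-5051, High-SCS-5189 or High-SCS-5217 (adjusted p = 0.246, 0.319, 0.0643, 0.0844 and 0.077).

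Over all probes, limma called 12 different between the lines in T5Sp, 6 in each direction, 1 in T5Sa, and 0 in Tref, T1Sa and T1Sp (408, 552 and 362 at an unadjusted p under 0.05) and over all conditions together (403). None of the 4 interactions of line and stimulation gave a call (100, 57, 80 and 108 at an unadjusted p under 0.05 in T1Sa, T1Sp, T5Sa and T5Sp), except 1 probe for T5Sp with the number as a block. The T5Sp line count was 3 with the slide as a random block, 0 and 2 on the arrays of scan days 1 and 2, and 21 with the array pair as a fixed term. It was 52 without Low-SCS-5046, 3 without Low-SCS-5051, 24 without Low-SCS-5093, 47 without Low-SCS-5127, 4 without High-SCS-5178, and 0 without Low-SCS-5129, Low-SCS-5130 or High-SCS-5217. The T5Sa count was 0 with the slide as a block (228 at an unadjusted p under 0.05) and on the arrays of each scan day (236 and 301), and leaving out numbers gave 0 to 3.

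Markers of other cell types showed no change that passed without the number as a block apart from CD14 in T5Sa. With it, CD14 passed in T1Sp (0.21, adjusted p = 0.0406, higher in 10 of 12 numbers) and T5Sp (0.24, adjusted p = 0.0351, higher in 10) too. Of the fibroblast markers, vimentin (VIM) stood at 11.64 ± 0.89 untreated and differed by at most 0.16 on the log2 scale in any stimulation (-0.16 ± 0.45 in T5Sp, lower in 9 of 12 numbers), and decorin (DCN) stood at 6.18 ± 0.13. The adipocyte marker FABP4 stood at 11.36 ± 1.03 and PLIN1 at 6.19 ± 0.07. The milk protein gene CSN2 stood at 7.03 ± 0.12 and did not pass in any stimulation.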

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

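The tests of explanations for TNF, for SLC2A3 and for the T1Sp count were chosen after those results had been seen; the search for single numbers far from the others was set before the data were examined.

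TNF after stimulation varied widely between numbers. In T1Sp its log2 intensity was 9.61 in High-SCS-5189, 9.15 in High-SCS-5217, 8.71 in Low-SCS-5093, 7.92 in Low-SCS-5130 and 7.81 in High-SCS-5071, and between 6.33 and 6.78 in the other 7, whereas all 12 lay between 5.98 and 6.23 untreated. Which RNA of an array a value belongs to rests on the dye labels. Numbers sharing arrays differed by up to 3.14, each line spanned at least 2.34 (3.28 in High-SCS), and the channels of a single slide spanned up to 3.50, which argues against a signal shared between array mates, the line and a slide-wide signal as whole explanations. The numbers highest in T1Sp were also the highest in T5Sa, on other arrays, at 8.38 to 9.53 against 6.25 to 6.92 in the other 7. In T5Sp High-SCS-5189, High-SCS-5217, Low-SCS-5093 and High-SCS-5071 were again the highest (7.32 to 7.98), but Low-SCS-5130 (6.57) lay within the range of the others. The size of the TNF response thus largely went with the number. Whether that reflects the animals or the cultures behind the numbers stays open and was not tested.

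SLC2A3 differed between the lines by 1.37 in T5Sp. The difference was 1.37 without the arrays whose channels resembled each other and at least 1.15 with any 1 number left out, which argues against those arrays and against a single number as the source of its size. The response to T5Sp did not differ detectably between the lines (interaction, unadjusted p = 0.139) and the untreated difference was 0.82, so a difference already present before stimulation stays open. The line itself stays open too, and the sign rests on the dye labels.

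The T1Sp count fell from 740 to 206 without the 6 arrays whose channels resembled each other. The 206 called without them, and 1947 without them and with the number as a block, argue against those arrays as the whole source of the changes. Of the 740, 149 stayed called without those arrays, and 559 were called without them and with the number as a block. The sign was kept by 737, and the changes of all 740 shrank to a median ratio of 0.681. These probes were picked with the arrays included, so the signs and the ratio decide nothing. The arrays may account for part of the 740. A true response to T1Sp stays open and was not separated from that part.

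In 98 searches, 5 values lay far from those of the other 5 numbers of the line, about as many as chance gives at 1 in 20. CXCL8 in T5Sp minus Tref was 5.88 in Low-SCS-5093 (the next highest was 2.18). That search compared numbers within a line only. In T5Sp CXCL8 stood at 13.84 in Low-SCS-5093 and at 12.4 to 13.24 in High-SCS-5071, High-SCS-5189 and High-SCS-5217. The other numbers lay between 7.7 and 11.62, and untreated all lay between 7.04 and 10.26. In T5Sa the 5 numbers with the highest TNF also had the highest CXCL8, at 12.58 to 13.89 against 8.34 to 10.85. Low-SCS-5093 was thus far from its line but not alone among the numbers. CCN1 in T5Sp was -1.37 in High-SCS-5217 (next -0.82) and 0.15 in Low-SCS-5129 (next -0.51). SCD in T5Sp was -0.83 in Low-SCS-5129 (next -0.36), and CCL25 in T1Sp was 0.51 in High-SCS-5012 (next 0.21).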

How the results depend on the processing

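The alternatives without the alike arrays (those whose channels resembled each other) and on single scan days were chosen after seeing the data; the others were planned. Of 82 gene results that passed, 2 kept their call in all alternatives and 1 changed sign in any. Calls were lost for 38 with median scaling, 32 without the dim filter, 25 and 15 on Cy5 and Cy3 alone, 20 without the alike arrays, 18 with processed signals, 9 of 60 in the value table, 3 with quantile normalisation, and 47 and 79 on scan days 1 and 2. With the number as a block 0 of 80 were lost; the other 2, line differences, cannot be fitted under it. Fewer arrays were fitted on single days; for the other changes below the cause was not tested.

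For T1Sa the count of 292 was 0 with median scaling (981 at an unadjusted p under 0.05 in limma), 106 without the dim filter, 473 in the value table and 125 on Cy5. It was 719 without the shared-array block, 1670 with the number as a block, 734 with the slide, 617 without the alike arrays and 2488 without them under the block. It was 1 and 0 on scan days 1 and 2. With 1 number left out it was 47 to 377 (47 without High-SCS-5182, 83 without Low-SCS-5046, 96 without Low-SCS-5130, 132 without High-SCS-5178, 146 without High-SCS-5217, 156 without High-SCS-5012, 163 without Low-SCS-5051).

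For T1Sp the count of 740 was 405 with median scaling, 447 without the dim filter, 1846 in the value table and 254 on Cy5. It was 1297 without the shared-array block, 2279 with the number as a block, 1284 with the slide, 206 without the alike arrays and 1947 without them under the block. It was 2 and 24 on scan days 1 and 2. Without single numbers it was 394 to 955 (394 without Low-SCS-5051, 468 without Low-SCS-5046, 475 without High-SCS-5189, 488 without High-SCS-5071).

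For T5Sa the count of 1326 was 878 on Cy5, 2739 with the number as a block, 3379 under it without the alike arrays and 53 on scan day 2. Single numbers left out gave 985 to 1425. For T5Sp the count of 292 was 114 with median scaling, 541 without the shared-array block, 1207 with the number as a block, 536 with the slide, 476 without the alike arrays, 1803 without them under the block and 13 on scan day 2. The range with 1 number left out was 199 to 272.

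For T1Sa against T1Sp the count of 3 was 0 with median scaling (1132 unadjusted in limma), 1 without the dim filter, 1376 in the value table, and 5 and 6 on Cy3 and Cy5. It was 6 without the shared-array block, 38 with the number as a block, 7 with the slide, 5 without the alike arrays, 42 without them under the block and 0 on both scan days. Leaving out numbers gave 1 to 6 (6 without Low-SCS-5046, 1 without Low-SCS-5129, High-SCS-5182 or High-SCS-5217). For T5Sa against T5Sp the count of 811 was 530 without the dim filter, 1685 in the value table and 528 on Cy5. It was 1300 without the shared-array block, 2347 with the number as a block, 1330 with the slide, 2983 under the block without the alike arrays and 20 on scan day 2. Leaving out numbers gave 541 to 882.

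Between the lines, the array pair as a fixed term gave 1 probe in Tref, 1 in T1Sa, 2 in T5Sa and 21 in T5Sp, and no dim filter gave 1 in T1Sa. Scan day 2 gave 2 in Tref. The 1 probe of T5Sa was 0 with median scaling, quantile normalisation, Cy3 or Cy5 alone, no shared-array block, the slide, and each scan day. The 12 of T5Sp were 2 with processed signals, 1 with median scaling, 4 with quantile normalisation, 6 in the value table, and 0 and 4 on Cy3 and Cy5. They were 3 without the shared-array block, 3 with the slide, 5 without the alike arrays, and 0 and 2 on scan days 1 and 2. The T5Sp interaction gave 1 with the number as a block, with or without the alike arrays. Leaving out numbers gave 0 to 2 in Tref (2 without High-SCS-5012 or High-SCS-5189), 0 to 4 in T1Sa (4 without High-SCS-5189, 2 without High-SCS-5012 or Low-SCS-5046, 1 without Low-SCS-5127 or High-SCS-5217), 0 to 0 in T1Sp, 0 to 3 in T5Sa (0 without High-SCS-5012, Low-SCS-5046, Low-SCS-5051, High-SCS-5189 or High-SCS-5217, 2 without High-SCS-5071, Low-SCS-5127, Low-SCS-5130 or High-SCS-5182, 3 without Low-SCS-5093), 0 to 52 in T5Sp, and 0 to 0 for the interactions and over all conditions.

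The 3 lists called were 6 with processed signals, 1 in the value table (of 12 list tests in place of 54), 6 on Cy3, 5 without the alike arrays and 1 with an estimated correlation. Leaving out numbers gave 2 to 6 (5 without Low-SCS-5051 or High-SCS-5071, 6 without Low-SCS-5129). Changed in sign were PCNA (0.21), ITGB6 (0.19) and FABP4 (0.25) in T1Sp under the block without the alike arrays, and SLC2A3 between the lines in T5Sp in the value table (-1.39), where each sample holds the values of the opposite channel.

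Signal over background limits dim genes: median signals of 38.2 to 60.5 in Cy3 lay close to backgrounds of 31 to 38. The sizes of dim genes varied with the processing. Over the alternatives the rise of MMP1 in T5Sp was 0.61 to 3.02 (main fit 0.87). In T5Sa the rises were 1.04 to 4.51 for TNF (1.44), 0.50 to 2.87 for PTX3 (0.78) and 0.44 to 2.18 for ICAM1 (0.54). Log2 sizes of dim genes, and counts of changes over 1, thus hold for the main processing only.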

Other observations

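The fits with the number as a block were planned; the genes of the first paragraph fall under the naming rule but were picked out after their values were seen, and the tests of other splits, including the one without the arrays whose channels resembled each other, were written after the counts were known.

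Some genes passed only with the number as a block, which raised the count of all probes from 292 to 1207 in T5Sp and from 740 to 2279 in T1Sp. Lactoferrin (LTF), an iron-binding antimicrobial protein, stood at 7.45 ± 1.33 untreated and 8.86 ± 1.73 in T5Sp, a difference of 1.41 ± 0.71 (adjusted p = 0.364; with the block 2.4e-09; higher in 12 of 12 numbers). In T5Sp the block also brought in the interferon-induced ISG15 (0.70, adjusted p from 0.185 to 0.0353, higher in 12), the interferon receptor chain IFNAR1 (0.37, 0.0768 to 5.41e-05, higher in 12) and the pattern receptor TLR2 (0.38, 0.0826 to 0.0042, higher in 11), whereas MX1 (0.50) stayed at 0.0764. PTGS2, the inducible prostaglandin synthase, differed by 0.87 in T1Sp (0.246 to 0.00203, higher in 12) and by 1.13 in T5Sp (0.207 to 0.000108, higher in 11), but its second probe differed by 0.11 and 0.17. TYMS, an enzyme of DNA synthesis, differed by -0.37 in T5Sp (0.0556 to 1.87e-06, lower in 12).

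Of the small lists that were not tested as a whole, none of 4 tight junction genes, 3 matrix and adhesion genes, 2 basal markers, 2 adipocyte markers or 2 fibroblast markers passed without the block in any stimulation. With the block, 2 tight junction genes rose in T1Sp and 1 in T5Sa, and 1 matrix and adhesion gene rose in T5Sa. The basal, adipocyte and fibroblast markers did not pass with it either. Endothelial markers and ribosome biogenesis had 0 measured genes.

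Other splits of the same samples were counted, 100 per comparison with the real one included. For the stimulations, splits that part every number as the real one does gave as many probes in 1 of 100, the real one itself. That is the smallest share that 100 splits can show. The counts were 287 for T1Sa (highest other 0), 732 for T1Sp (1), 1309 for T5Sa (236), 282 for T5Sp (20), 3 for T1Sa against T1Sp (1) and 804 for T5Sa against T5Sp (0), on the 8844 probes with a value in every RNA. For the 4 stimulations and T5Sa against T5Sp this argues against chance. The same splits with the number as a block gave as many in 1 of 100 too: 1630 for T1Sa (highest other 51), 2248 for T1Sp (103), 2697 for T5Sa (1024), 1190 for T5Sp (364), 38 for T1Sa against T1Sp (1) and 2309 for T5Sa against T5Sp (174). Of the 99 other splits, 1, 12, 13, 15, 3 and 13 gave calls under it, against 0, 1, 3, 2, 1 and 0 without it. For T1Sa against T1Sp, splits free to keep a number together gave as many in 4 of 100, the highest with 132. Its count was 1 to 6 with 1 number left out, so chance cannot be excluded there. For the 12 line differences in T5Sp, 2 of 100 splits gave as many (highest other 51), but of the 32 splits that part every array pair 3 did (highest 33), so chance cannot be excluded among those. For the 1 probe of T5Sa, 5 of 100 did (highest 3), and chance cannot be excluded. For Tref, T1Sa, T1Sp, all conditions and the 4 interactions the real count was 0 in limma, so 100 of 100 gave as many (highest other 2, 0, 562, 14, and 0, 0, 0 and 5). The split of T1Sp with 562 probes set High-SCS-5012, Low-SCS-5051, High-SCS-5071, Low-SCS-5093, Low-SCS-5129 and High-SCS-5189 against the rest, which points to a structure of the samples. It was the only one of the 99 other splits to keep together the 4 RNAs of the T1Sp arrays whose channels resembled each other, and the other 98 gave at most 82. Without those arrays it gave 2 probes. Those arrays may be its source, but it was picked as the highest, so this stays open. For the 3 lists, the calls were summed over the 6 comparisons, with 1 split of each. Of 100 such sums, 9 gave as many (highest other 5, median 1, and 70 of the other 99 held at least 1), so chance cannot be excluded for the number of lists. This count does not weigh how low the p of a list was, so it does not judge any single list.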
